A study of Mus musculus with 8 samples.

How the data were processed

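The series holds RNA sequencing of mouse bone marrow derived macrophages in 4 groups of 2 libraries: PBS or spermine, each at 0 h and 3 h of IFN-β. Groups and replicate numbers were taken from the sample titles. The series text names DMSO where the sample labels name PBS, and the labels' name is used. The extraction protocol names blood as the source of the RNA while the sample labels give macrophages, and the macrophages are taken as the source. Spermine dose, length of spermine treatment and IFN-β dose are not given in the sources used here. Per the labels, mRNA was purified from total RNA on poly-T beads and primed with random hexamers, and the strand is not stated. Dates, sequencing runs and the mice behind each library are not given in the sources used here.

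The table deposited by the authors gives FPKM (fragments scaled by gene length and library size) for 54532 genes in 8 libraries, with the gene length in bases, the gene biotype and positions. Per the submitters' processing notes, which name tools without their order or role, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the genome builds GRCm38 and mm10 were used. How reads that map to several genes were counted is not given in the sources used here. Deposited FPKM times gene length was a whole multiple of a single step per library for 100% of values, within a tolerance of 0.001 of a read, so the reads were rebuilt by dividing by that step. The step equals what median-of-ratios size factors would give, so the deposited scale is not the library total but a factor that holds the median gene steady. Rebuilt totals lay between 15723437 and 17744844 reads per library, and 25062 genes had a read in any library. Of the gene identifiers 54495 are in GENCODE M21, and of these 98.3% have the same position there. Where a symbol is given to several rows, the row with the most reads was used for it, which left 103 rows unnamed by symbol.

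Genes with an FPKM of at least 1 in at least 2 of the 8 libraries were kept, 11421 in all, of which 9810 are protein coding. Log2(FPKM + 1) was fitted with limma 3.58.1 (R 4.3.3, data.table version 1.17.8) as 4 group means over the 8 libraries, with 4 residual degrees of freedom and empirical Bayes moderation with an intensity trend (2.83 prior degrees of freedom). There were 5 comparisons: 3 h against 0 h of IFN-β in PBS, the same with spermine, spermine against PBS at 0 h, the same at 3 h, and the difference of the IFN-β responses, spermine minus PBS. The limma tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p under 0.05 are said to have changed. An adjusted p for 1 comparison does not correct for the other comparisons. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

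Before the data were examined, 24 gene lists, 7 sets of markers of other cells, the model, the thresholds, most alternatives and a rule for the genes to name were fixed. The lists cover antiviral interferon-stimulated genes, interferon-inducible GTPases, the interferon receptor with its kinases and ISGF3, feedback regulators, interferon-inducible chemokines and cytokines, NF-κB inflammatory genes, MHC class I, MHC class II, and nucleic acid sensing with the inflammasome and lytic death. They also cover polyamine metabolism, cholesterol biosynthesis, sterol efflux, the integrated stress response, NRF2 targets, the unfolded protein response, heat shock, glycolysis and hypoxia, the lysosome, the cell cycle, immediate early genes, macrophage identity, alternative activation, mitochondrial mRNAs and histones. Lists share some genes, such as Slc7a11, and Pyhin1, Cgas, Mnda and Sting1 are not in the table under those names. Each list was tested with camera in limma at a preset correlation between genes of 0.01, and its p-values were adjusted over the 24 lists of a comparison. Camera compares the list with all other genes. The same test with the correlation estimated from the data, and fry, which tests whether a list's genes move on balance one way, were run beside it. With the estimated correlation only the NRF2 list passed, in spermine against PBS at 0 h and at 3 h. Calls were also lost where the estimate lay below the preset 0.01, such as -0.04 for NF-κB genes and -0.082 for heat shock genes. The antiviral list did not pass either where all 39 members rose with IFN-β in PBS (adjusted p = 0.0719). A call lost in this test therefore does not show that a list was unchanged. Members that pass are counted over all genes and also adjusted over the list alone.

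The rule for named genes has 3 parts. The first always names Jak1, Tyk2, Ifnar1, Ifnar2, Stat2, Irf9, Irf7, Socs1, Usp18, Isg15, Ifit1, Mx1, Rsad2, Cxcl10, Odc1, Amd1, Sat1, Smox, Srm, Sms and Oaz1. The second takes, for each comparison, up to 8 rising and 8 falling protein-coding genes of the largest change whose groups do not overlap (a condition not set for the difference of the responses) and whose higher group has a mean FPKM of at least 5. The third takes up to 4 changed members of each list and comparison, or, where none changed, up to 2 with the largest log2 change. The text gives 107 genes out of these, and 2 others that the rule names are not reported here. The differences of response in the closing section include genes that the rule names in other comparisons only.

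The fit was tested on simulated data: reads for the real genes with a dispersion of 0.01, of which 200 were changed in 1 group of 2 libraries per comparison. It recovered 24.2%, 82.5% and 95.4% of changes of 1.5-fold, 2-fold and 4-fold in the IFN-β comparison in PBS, and 19.4%, 64.5% and 92.3% in that with spermine. For spermine against PBS it recovered 15.3%, 73.4% and 93.8% at 0 h and 15.6%, 66.7% and 93.8% at 3 h. For the difference of the responses it recovered 0%, 26.2% and 85.9%. False calls made up 5.15%, 7.44%, 5.69%, 10.9% and 6.49% of all calls in the 5 comparisons. All simulated genes had the same dispersion and 200 were changed, while 1550 to 5661 genes changed in the data. These rates of recovery and of false calls therefore need not hold for the data. The replicates differed by more than read sampling: the chi-square per degree of freedom, over genes with at least 20 reads in the pair, was 7.12 and 14.6 for PBS at 0 h and 3 h, and 12.8 and 4.03 for spermine.

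Alternatives changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, a filter of FPKM at least 5, rescaling to TPM, median-of-ratios rescaling, quantile normalization, empirical Bayes without a trend, a fit of only the groups compared, a block for the replicate number, limma voom on the rebuilt reads, protein-coding genes only, a limit of 1 log2 unit, and each library left out in turn. Where a library is left out, the lone library of its group is assumed to vary like the other groups. For 2 comparisons that share libraries, the covariance of changes is given beside 100 simulations of unchanged groups with the same sharing, and the overlap of calls beside that of independent lists and that with the shared libraries split, 1 to each comparison. Exact permutation tests were not used, since 2 libraries against 2 cannot reach a small p.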

Results

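The data are RNA sequencing libraries, made from poly(A)-selected RNA of mouse bone marrow derived macrophages, immune cells grown from marrow that engulf microbes and debris. The cells had received PBS, a salt buffer used as control, or spermine, a small positively charged polyamine that cells also make themselves. The labels give 0 h or 3 h of IFN-β, the type I interferon that switches on antiviral genes. No group was kept for 3 h without IFN-β. A change from 0 h to 3 h, below called a change with IFN-β, therefore also holds any effect of those 3 h alone. Each of the 4 groups (PBS 0 h, PBS 3 h, spermine 0 h and spermine 3 h) holds 2 libraries, and the labels do not say whether these come from separate animals or cultures, so the p-values measure a spread between libraries that may be technical. Reads rebuilt from the deposited FPKM came to between 15723437 and 17744844 per library, and 11421 genes with an FPKM of at least 1 in at least 2 libraries were tested with limma. Every change is a log2 change of FPKM + 1, which understates the change of genes near or below 1 FPKM, and levels are the mean FPKM ± SD (n = 2 libraries). The deposited scaling leaves the median gene near no change, so a change is relative to the median gene. Rescaling to TPM shifted each gene's change, with a median shift over genes of -0.40 for IFN-β in PBS and -0.28 for IFN-β with spermine. That median shift was -0.30 for spermine at 0 h, -0.17 for spermine at 3 h and 0.13 for the difference of the responses.

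What did macrophages switch on and off in the 3 h after IFN-β without spermine? They turned on the whole measured antiviral program, from genes of almost no transcript to some of the most abundant in the cell. Genes that present peptides on MHC class I, that call other immune cells and that sense foreign nucleic acids rose with them. In all, 5661 of the 11421 genes changed, 2807 rising and 2854 falling, and of those that moved by at least 1 log2 unit 1233 rose and 522 fell. The share of changed genes that rose was 49.6%, against 21.1% after TPM rescaling and 36.6% after quantile normalization, so the balance of rising and falling genes depends on the scaling.

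All 39 measured antiviral genes rose (median log2 change 4.90, adjusted p = 1.66e-28, and adjusted p = 0.0719 with an estimated correlation). Rsad2, which encodes viperin, a blocker of viral replication, went from 3.08 ± 0.222 to 4779 ± 489 FPKM (log2 change 10.19 ± 0.09 SE, adjusted p = 1.2e-08). Its neighbour Cmpk2, a mitochondrial nucleotide kinase, reached 3036 FPKM. Ifit1 and its relative Ifit1bl1, which bind viral RNA, rose by 8.89 and 10.59, Mx1, which traps viral particles, by 8.68, and the ubiquitin-like tag Isg15 by 6.89. Near-identical family copies such as Ifit1bl1 share reads, and how shared reads were counted is not given in the sources used here. Antiviral genes made up 0.34% ± 0.0122 of all reads at 0 h and 9.43% ± 0.607 at 3 h. The interferon-inducible GTPases, which attack the vacuoles that hold bacteria and parasites, rose in 16 of 16 members (median 6.39, adjusted p = 3.07e-15, and adjusted p = 0.168 with an estimated correlation), with Iigp1 up by 9.24 and Gbp2 by 8.38. All 14 measured interferon-inducible chemokines and cytokines rose (median 4.37, adjusted p = 3.98e-12, and adjusted p = 0.0719 with an estimated correlation). Among them, Cxcl10, which draws T cells into tissue, went from 0.703 ± 0.184 to 2934 ± 91.7 FPKM (log2 change 10.76) and the death ligand Tnfsf10 rose by 7.30. The list of nucleic acid sensing, inflammasome and lytic death genes, below called the sensing and death list, rose in 17 of 17 members (median 2.97, adjusted p = 4.35e-12, and adjusted p = 0.179 with an estimated correlation), including the DNA-binding Ifi205 (6.68) and Ifi203 (5.84). MHC class I genes rose in 19 of 20 members (median 2.25, adjusted p = 4.35e-12, and adjusted p = 0.0719 with an estimated correlation), led by H2-T24 (4.14) and Nlrc5 (3.98), the activator of the class. Adjusted over the list alone, the counts of rising genes were the same for these lists, except MHC class I with 20.

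The genes that carry and damp the signal also moved. Of 14 genes of the interferon receptor, its kinases and ISGF3, the transcription factor that the signal assembles, 12 rose and 1 fell, the same counts adjusted over the list alone (median 1.13, adjusted p = 0.000105, and adjusted p = 0.095 with an estimated correlation). The ISGF3 genes Stat2 and Irf9 rose by 4.06 and 2.37, and the kinase Jak2 by 2.65. Jak1 (ENSMUSG00000028530, chromosome 4, 101152367 to 101265282 in GRCm38), the kinase bound to the IFN-β receptor that the series title names, went from 29.3 ± 1.17 to 36.3 ± 1.85 FPKM (log2 change 0.30, adjusted p = 0.0201). Its sign depends on the scaling (-0.16 after TPM rescaling, -0.12 after quantile normalization), and the call was lost without PBS 0 h replicate 1 (0.34) or 2 (0.26) or PBS 3 h replicate 1 (0.25). Its partner Tyk2 rose by 0.70, or 0.25 after TPM rescaling (adjusted p = 0.124). The receptor gene Ifnar1 fell by 0.31 (adjusted p = 0.0102), a call lost without PBS 0 h replicate 1 (-0.25). Ifnar2 had a log2 change of 0.18 (adjusted p = 0.047) that reversed after TPM rescaling (-0.28) and quantile normalization (-0.26), and it passed in only 1 of the 8 fits that left out 1 library. It was also lost, at 0.18, without a trend and in a fit of only the 2 groups, and with limma voom (0.19). Without PBS 3 h replicate 1 it was 0.13, and without each of the other 6 libraries that ended the call it lay between 0.18 and 0.19. Feedback regulators rose in 8 of 10 members and fell in 1, or rose in 9 adjusted over the list alone (median 2.73, adjusted p = 2.04e-05, and adjusted p = 0.0852 with an estimated correlation). Socs1, which blocks the JAK kinases, went from 0.159 to 204 ± 65.7 FPKM (log2 change 7.43), and Usp18, which strips Isg15 and mutes the receptor, rose by 6.92. The transcription factors Irf7 and Irf1 rose by 4.57 and 4.38. NF-κB inflammatory genes rose in 14 of 19 and fell in 3, the same counts adjusted over the list alone (median 1.27, adjusted p = 3.97e-05, and adjusted p = 0.0719 with an estimated correlation), with the chemokine Ccl4 up by 6.45 and the costimulatory receptor Cd40 by 5.30. The Fc receptor Fcgr1 rose by 3.55. Among the largest falls were the lipid receptor S1pr1 (-2.99), the GTPase activator Fgd3 (-2.84), the anion transporter Slc26a11 (-2.75) and Sesn1 (-2.70), a p53 target that restrains growth.

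**Figure D1:**
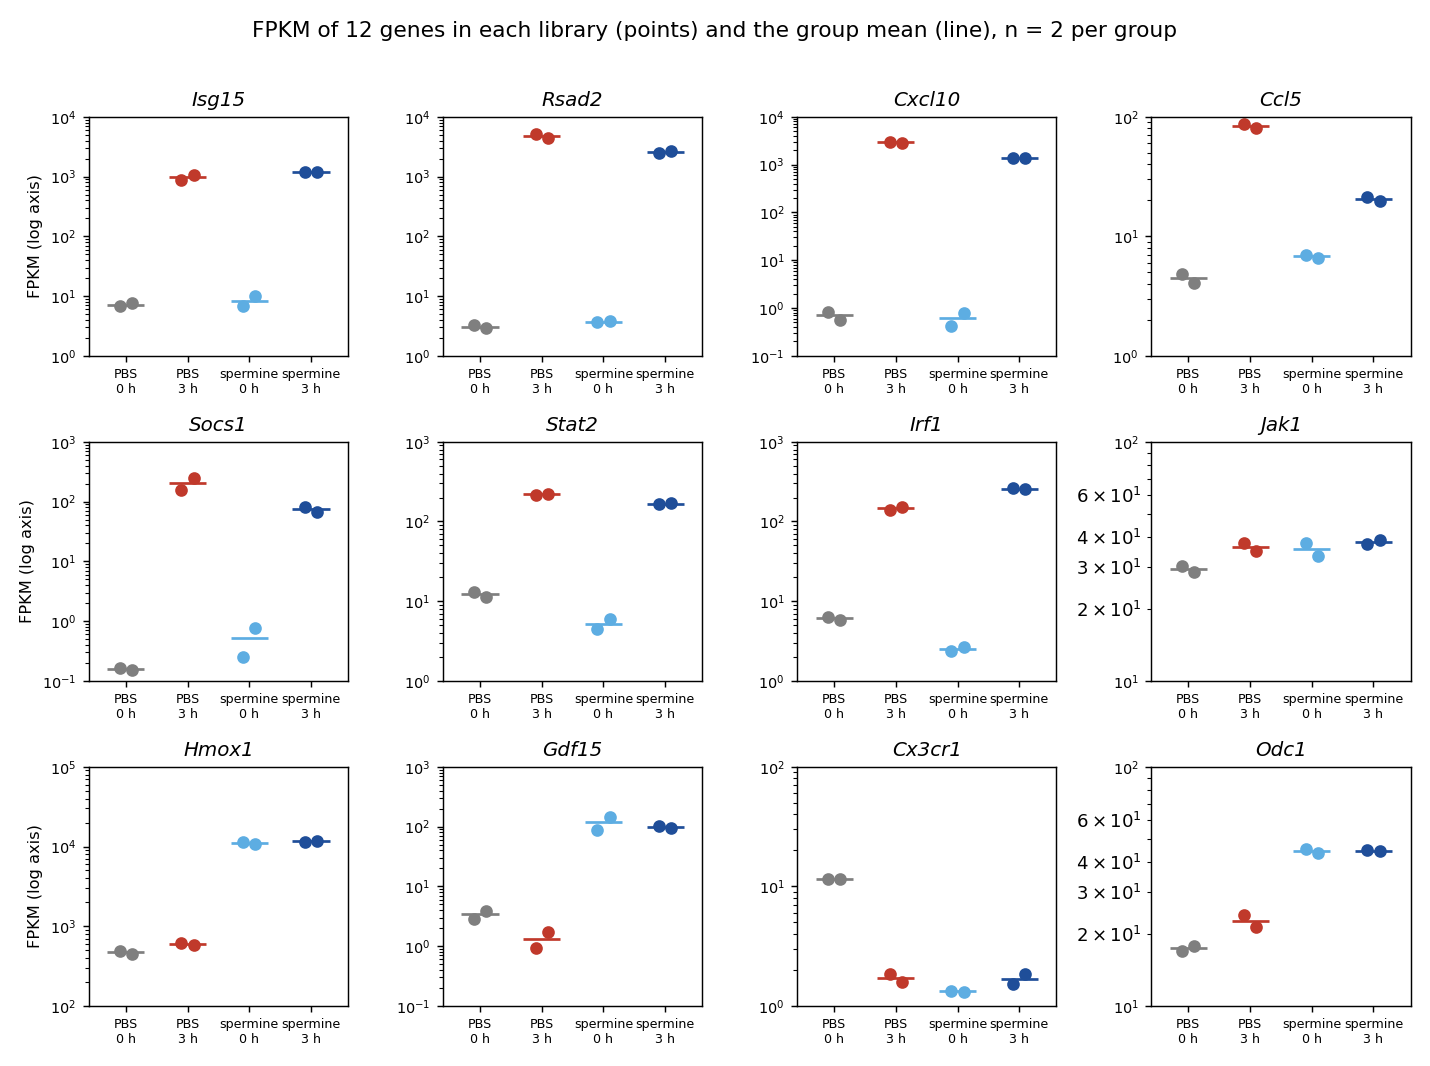
FPKM on a log axis of 12 genes in each of the 8 libraries (points, with the group mean as a line), for PBS and spermine at 0 h and 3 h of IFN-β. Rsad2, Cxcl10, Ccl5 and Socs1 sit lower at 3 h with spermine than with PBS, Irf1 sits higher, and Hmox1 and Gdf15 are high in both spermine groups.

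Did macrophages given spermine still respond to IFN-β? They did, with the same families of genes: every measured antiviral gene, GTPase, interferon-inducible chemokine and cytokine, and member of the sensing and death list rose again. Of the 11421 genes, 4768 changed, 2248 rising and 2520 falling, and of those that moved by at least 1 log2 unit 855 rose and 214 fell. The share of changed genes that rose was 47.1%, against 21.5% after TPM rescaling and 33.6% after quantile normalization. The 39 antiviral genes had a median log2 change of 4.63 (adjusted p = 1.16e-34, and adjusted p = 0.0573 with an estimated correlation). Cmpk2 rose by 10.0, Ifit1 by 9.32, Rsad2 by 9.06, Ifit1bl1 by 9.12 and Mx1 by 7.80. Isg15 went from 8.38 ± 2.24 to 1199 ± 7.83 FPKM (log2 change 7.02). The GTPases rose in 16 of 16 members (median 6.73, adjusted p = 5.65e-18, and adjusted p = 0.131 with an estimated correlation), with Igtp, which guards against vacuolar parasites, up by 7.52. Chemokines and cytokines rose in 14 of 14 (median 3.39, adjusted p = 3.73e-13, and adjusted p = 0.0573 with an estimated correlation), with Cxcl10 up by 9.76. The sensing and death list rose in 17 of 17 (median 2.65, adjusted p = 9.66e-14, and adjusted p = 0.145 with an estimated correlation). MHC class I genes rose in 19 of 20, or 20 adjusted over the list alone (median 2.0, adjusted p = 1.56e-13, and adjusted p = 0.0573 with an estimated correlation), led by the peptide pump Tap1 (4.96). Of the receptor, kinase and ISGF3 genes 10 of 14 rose, or 12 adjusted over the list alone (median 0.74, adjusted p = 5.69e-07, and adjusted p = 0.0573 with an estimated correlation), with Stat2 up by 4.77, Irf9 by 2.91 and Ifnar2 by 0.65. Feedback regulators rose in 8 of 10 and fell in 1 (median 3.16, adjusted p = 1.99e-06, and adjusted p = 0.0573 with an estimated correlation), with Usp18 up by 6.83, Irf1 by 6.21, Socs1 by 5.64 and Irf7 by 4.0. NF-κB genes rose in 12 of 19 and fell in 2, or 13 and 2 adjusted over the list alone (median 0.81, adjusted p = 0.000409, and adjusted p = 0.0573 with an estimated correlation), with Ccl4 up by 4.48 and the fever cytokine Il6 by 3.74. The largest falls included the oxygen sensor Egln3 (-1.93), the receptor-signalling inhibitor Spry3 (-1.87) and the TGF-β receptor Tgfbr1 (-1.73). The list counts not given here for adjustment over the list alone equalled those over all genes.

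What did spermine do before IFN-β was added? In macrophages given spermine, most measured genes that detoxify oxidants, refold proteins, respond to amino acid shortage and burn sugar were higher at 0 h than with PBS, and of these lists only that of the NRF2 targets passes with an estimated correlation (adjusted p = 0.0333, against 0.0977 for heat shock, 0.117 for the unfolded protein response, 0.0779 for the integrated stress response and 0.199 for glycolysis). The NF-κB inflammatory genes were higher as a list as well (0.117 with an estimated correlation). Of the antiviral genes 18 were lower and 7 higher, and the receptor and kinase genes of the interferon pathway went both ways. Of the 11421 genes, 4706 changed, 2510 rising and 2196 falling, or 2999 without PBS 0 h replicate 2. Of those that moved by at least 1 log2 unit, 493 rose and 257 fell. The share of changed genes that rose was 53.3%, against 20.1% after TPM rescaling.

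The NRF2 targets, which defend against oxidants, rose in 17 of 18 members, the same count adjusted over the list alone (median 2.17, adjusted p = 2.04e-12, and adjusted p = 0.0333 with an estimated correlation). Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), which breaks down haem, went from 469 ± 29.4 to 10980 ± 425 FPKM (log2 change 4.55 ± 0.07 SE, adjusted p = 9.17e-07). Gclc, which makes glutathione, rose by 3.32, the sulfinic acid reductase Srxn1 by 3.0, and the cystine importer Slc7a11, a member of the NRF2 and the integrated stress lists, by 3.68. NRF2 targets made up 2.86% of reads with PBS and 6.66% with spermine. The integrated stress response rose in 13 of 19 members, or 14 adjusted over the list alone (median 1.09, adjusted p = 2.53e-06, and adjusted p = 0.0779 with an estimated correlation), with its transcription factor Atf4 up by 1.65, the phosphatase subunit Ppp1r15a by 3.39 and Ddit4, a brake on mTOR, by 2.45. Heat shock genes rose in 8 of 10, the same count adjusted over the list alone (median 1.10, adjusted p = 0.000153, and adjusted p = 0.0977 with an estimated correlation), with the chaperones Hspa1a (2.26) and Hsp90aa1 (1.62). Hspa1a has a near-identical copy, so reads of the pair cannot be assigned with certainty. NF-κB genes rose in 10 of 19 and fell in 2, the same counts adjusted over the list alone (median 0.40, adjusted p = 0.00469, and adjusted p = 0.117 with an estimated correlation). The prostaglandin synthase Ptgs2 rose from 0.394 ± 0.0858 to 12.4 ± 0.662 FPKM, the neutrophil attractant Cxcl2 by 3.11 and Tnf by 1.76. Outside the lists, the stress cytokine Gdf15 rose from 3.38 ± 0.784 to 118 ± 40.3 FPKM (log2 change 4.73), the endothelin receptor Ednrb by 4.43, the protein C receptor Procr by 4.24 and the AP-1 subunit Fosl1 by 3.69. Large falls included Enc1 (-2.81), an actin-binding repressor of NRF2, Sesn1 (-2.49), the fractalkine receptor Cx3cr1 (-2.43) and Tor4a (-2.34).

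In the interferon pathway, 18 of 39 antiviral genes were lower with spermine at 0 h and 7 higher, or 21 and 8 adjusted over the list alone (median -0.34, adjusted p = 0.0107, and adjusted p = 0.512 with an estimated correlation). Slfn5 (-0.97), Ifit1 (-0.96), the RNA-degrading pathway's Oas2 (-0.94) and Parp14 (-0.91) fell, the RNA sensor regulator Oasl1 rose (0.69), and Cxcl10 did not pass (-0.09, adjusted p = 0.584, with values of 0.02 without PBS 0 h replicate 1 and 0.07 without spermine 0 h replicate 1). GTPases fell in 7 of 16, the same count adjusted over the list alone (median -0.19, adjusted p = 0.0112, and adjusted p = 0.512 with an estimated correlation), with Irgm2 down at -1.10 and Ifi47 at -1.07. The GTPase call was lost after TPM rescaling (median -0.29). MHC class I genes fell in 9 of 20 and rose in 2, or 9 and 3 adjusted over the list alone (median -0.27, adjusted p = 0.029, and adjusted p = 0.421 with an estimated correlation), with Tap1 at -1.11. That list call was lost without spermine 0 h replicate 1 (median -0.17) and with limma voom (-0.33). The sensing and death list fell in 6 of 17 and rose in 2, with no list call (median -0.20, adjusted p = 0.133) except without PBS 0 h replicate 2 (-0.27) or spermine 0 h replicate 1 (-0.26), and the CpG DNA receptor Tlr9 fell by 1.41. The receptor and kinase list went both ways, 4 higher and 6 lower of 14, the same counts adjusted over the list alone (median -0.10, adjusted p = 0.302). With fry that list passed at 0 h (adjusted p = 0.00723). Ptpn6, a phosphatase that ends cytokine signals, fell from 63.2 ± 0.617 to 17.9 ± 0.908 FPKM, Stat2 fell by 1.10 and Ifnar1 by 0.52, and the phosphatase Ptpn1 rose by 1.39. Irf9 fell by 0.42, a call lost without PBS 0 h replicate 1 (-0.38) or spermine 0 h replicate 1 (-0.29) or in a fit of only the 2 groups (-0.42), and Tyk2 fell by 0.57, a call lost without PBS 0 h replicate 2 (-0.51) or spermine 0 h replicate 1 (-0.40). Jak1 had a log2 change of 0.27 (adjusted p = 0.0354), which TPM rescaling turned to -0.07. The Jak1 call was lost after quantile normalization (0.03), at the same 0.27 without a filter, without a trend and in a fit of only the 2 groups, and without PBS 0 h replicate 1 (0.31) or 2 (0.23) or spermine 0 h replicate 1 (0.18), and, with the value itself unmoved at 0.27, without either spermine 3 h library. Feedback regulators rose in 2 and fell in 4 of 10, the same counts adjusted over the list alone, with a median of 0.10 against a mean of -0.03 and a test pointing down (adjusted p = 0.598). With fry the feedback list passed at 0 h (adjusted p = 0.0498). Socs3, which damps cytokine receptors, rose by 1.55, Irf1, Irf8 and Usp18 fell by 1.02, by 1.22 and by 0.58. Interferon-inducible chemokines and cytokines rose in 4 and fell in 1 of 14, the same counts adjusted over the list alone (median 0.01, adjusted p = 0.598).

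Did added spermine change the cells' own polyamine genes? Of 22 measured genes of polyamine metabolism and transport, 8 rose and 4 fell at 0 h, the same counts adjusted over the list alone, without a list call (median 0.12, adjusted p = 0.235, and -0.12 after TPM rescaling). At 3 h 11 rose and 5 fell, again the same adjusted over the list alone (median 0.34, adjusted p = 0.189). With fry the list passed at 0 h and at 3 h (adjusted p = 0.00252 and 0.00515). Odc1 (ENSMUSG00000011179, chromosome 12, 17544794 to 17551505), the first enzyme of synthesis, rose from 17.4 ± 0.635 to 44.3 ± 1.12 FPKM at 0 h (log2 change 1.30, adjusted p = 4.14e-05) and by 0.95 at 3 h. Amd1, the next rate-limiting enzyme, fell by 1.09 at 0 h and by 1.46 at 3 h, with reads that it shares with its copy Amd2. The breakdown enzymes rose: Sat1, which acetylates spermine, by 0.67 at 0 h and 0.51 at 3 h, and Smox, which oxidises it, by 0.94 and 1.10. The amino acid and polyamine carrier Slc3a2 rose by 1.40 and 1.26. At 3 h the spermine synthase Sms fell by 0.58 and the spermidine synthase Srm rose by 0.55, a call lost without PBS 3 h replicate 1 (0.43) or spermine 3 h replicate 1 (0.43). Oaz1, the brake on Odc1, had a log2 change of 0.72 at 3 h (adjusted p = 0.0458). That call was lost without PBS 3 h replicate 1 (0.46), spermine 3 h replicate 1 (0.64) or 2 (0.80), or, at an unmoved 0.72, without either PBS 0 h library. It was lost too after TPM rescaling (0.52) and quantile normalization (0.50), and at 0.72 without a filter or without a trend. From 0 h to 3 h of IFN-β in PBS some of these genes moved: Sat1 by 1.09, Smox by 1.11, Srm by -0.99 and Sms by 0.55 (or 0.15 after TPM rescaling, adjusted p = 0.234). With spermine Sat1 moved by 0.93 and Smox by 1.27. The whole list showed no call for IFN-β in PBS (8 higher and 4 lower, median 0.15, adjusted p = 0.424) or with spermine (7 and 4, median 0.11, adjusted p = 0.459), and both medians turned negative after TPM rescaling (-0.26 and -0.17). With fry the list passed for IFN-β in PBS and with spermine (adjusted p = 0.00615 and 0.0404).

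**Figure D2:**
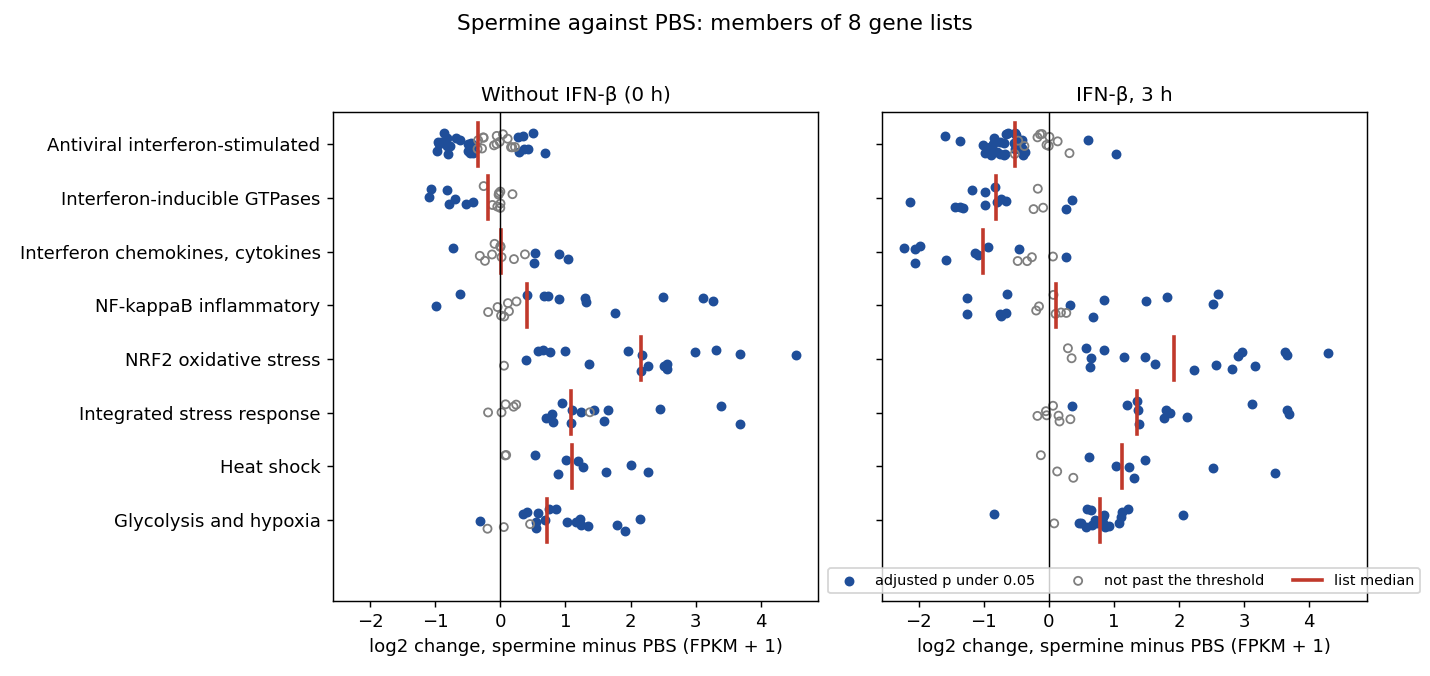
Log2 change of FPKM + 1 with spermine against PBS for each member of 8 gene lists, at 0 h (left) and at 3 h of IFN-β (right), with filled points for an adjusted p under 0.05, open points for the rest and a line at the list median. At 3 h the antiviral, GTPase and chemokine medians lie at -0.52, -0.82 and -1.01, and the NRF2 median lies at 2.17 at 0 h and 1.93 at 3 h.

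Was the transcript level of interferon-stimulated genes lower with spermine at 3 h of IFN-β? Many were: the antiviral genes, GTPases, chemokines and cytokines, sensing and death genes and MHC class I genes were lower as lists, calls that an estimated correlation takes away (adjusted p = 0.26, 0.353, 0.169, 0.353 and 0.203), and Isg15 was not lower. The stress lists that were higher at 0 h were higher at 3 h too, and with an estimated correlation that of the NRF2 targets passes (0.0299) and those of the integrated stress response (0.0926), heat shock (0.0964), glycolysis (0.169) and the unfolded protein response (0.169) do not. Of the 11421 genes, 4626 differed, 2276 higher and 2350 lower, or 2912 without spermine 3 h replicate 1. Of those that differed by at least 1 log2 unit, 446 were higher and 374 lower. The share that was higher was 49.2%, against 26.4% after TPM rescaling.

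Of 39 antiviral genes 26 were lower and 2 higher, or 29 and 2 adjusted over the list alone (median -0.52, adjusted p = 1.57e-06, and adjusted p = 0.26 with an estimated correlation). Ifi44 (-1.60), Ifit1bl1 (-1.37), the ubiquitin ligase Herc6 (-1.02), Mx1 (-0.98) and Rsad2 (-0.91, 2540 ± 139 against 4779 ± 489 FPKM) fell. Oasl1 rose (1.04), while Isg15 (0.32, adjusted p = 0.18) and Ifit1 (-0.53, adjusted p = 0.0737) did not pass. Ifit1 passed at the same -0.53 without either PBS 0 h library, in a fit of only the 2 groups and among protein-coding genes only, at -0.73 after TPM rescaling and at -0.52 with limma voom, with which Isg15 passed at 0.32. The list took 9.43% ± 0.607 of reads with PBS and 6.1% ± 0.193 with spermine. GTPases fell in 11 of 16 and rose in 2, the same counts adjusted over the list alone (median -0.82, adjusted p = 9.24e-05, and adjusted p = 0.353 with an estimated correlation), with Gbp11 (-2.14) and Gbp4 (-1.44) the lowest of those named by the fixed rule, in a family whose copies share reads. Chemokines and cytokines fell in 9 of 14 and rose in 1, or 10 and 1 adjusted over the list alone (median -1.01, adjusted p = 5.07e-05, and adjusted p = 0.169 with an estimated correlation). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) stood at 1382 ± 5.95 FPKM against 2934 ± 91.7 (log2 change -1.09 ± 0.12 SE, adjusted p = 0.000626). Its neighbour Cxcl9 stood at 16.9 ± 0.181 against 83.6 ± 13.3 (-2.23), Tnfsf10 at -2.06, the cytokine subunit Il27 at -2.06 and the T cell attractant Ccl5 at -1.98. MHC class I genes fell in 13 of 20, or 15 adjusted over the list alone (median -0.33, adjusted p = 0.00027, and adjusted p = 0.203 with an estimated correlation), with H2-T24 at -1.58. The sensing and death list fell in 8 of 17, or 10 adjusted over the list alone (median -0.44, adjusted p = 0.000189, and adjusted p = 0.353 with an estimated correlation), with the RNA receptor Tlr3 at -1.90 and Tlr9 at -1.29. Other large falls were Sectm1a (-2.79), Tnfsf8 (-2.39) and the nucleotide receptor P2ry13 (-2.36).

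The pathway's own genes went both ways at 3 h. Of the 14 receptor, kinase and ISGF3 genes 2 were higher and 5 lower, or 3 and 5 adjusted over the list alone (median -0.06, adjusted p = 0.461). With fry that list passed at 3 h (adjusted p = 0.00953). Ptpn6 fell by 0.97 and Tyk2 by 0.91, and Ptpn1 rose by 1.08. Jak1 stood at 38.0 ± 0.999 against 36.3 ± 1.85 FPKM (log2 change 0.07, adjusted p = 0.554, and -0.14 after TPM rescaling), and Ifnar1 (-0.08) and Irf9 (0.13) did not pass either, except Ifnar1 after TPM rescaling (-0.28). Ifnar2 rose by 0.32, a call lost after TPM rescaling (0.12) and quantile normalization (0.18) and without spermine 3 h replicate 2 (0.30). Stat2 had a log2 change of -0.39 (adjusted p = 0.0407), a call lost with a pseudocount of 0.1, without a filter and without a trend (all -0.39) and without PBS 3 h replicate 1 (-0.41) or 2 (-0.37) or spermine 3 h replicate 1 (-0.36) or 2 (-0.42). Feedback regulators rose in 4 and fell in 4 of 10, the same counts adjusted over the list alone, with a median of -0.08, a mean of 0.13 and a test pointing up (adjusted p = 0.923). With fry the feedback list passed at 3 h (adjusted p = 0.0345). Socs1 fell from 204 ± 65.7 to 73.7 ± 8.69 FPKM (log2 change -1.43) and Usp18 by 0.67, while Socs3 rose by 2.09 and Irf1 by 0.81. Irf7 fell by 0.44, a call lost without a filter (-0.44) and without PBS 3 h replicate 2 (-0.32) or spermine 3 h replicate 1 (-0.47) or 2 (-0.41). NF-κB genes rose in 7 and fell in 6 of 19, or 8 and 6 adjusted over the list alone (median 0.10, adjusted p = 0.449, and -0.05 after TPM rescaling). With fry the NF-κB list passed at 3 h (adjusted p = 8.85e-05). Cxcl2 (2.61), Ptgs2 (2.52), the inflammasome product Il1b (1.82) and Il6 (1.49) were higher. NRF2 targets rose in 16 of 18, or 17 adjusted over the list alone (median 1.93, adjusted p = 4.06e-13, and adjusted p = 0.0299 with an estimated correlation), with Hmox1 up by 4.29, Srxn1 by 3.63, and Osgin1, an oxidative stress growth inhibitor, by 3.16. The integrated stress response rose in 12 of 19, or 13 adjusted over the list alone (median 1.36, adjusted p = 4.63e-06, and adjusted p = 0.0926 with an estimated correlation), with Ddit4 (3.69), Slc7a11 (3.66) and Ppp1r15a (3.13). Heat shock genes rose in 7 of 10, or 8 adjusted over the list alone (median 1.13, adjusted p = 0.000102, and adjusted p = 0.0964 with an estimated correlation), with Hspa1a (3.48) and Hsp90aa1 (1.31). Gdf15 (5.45), the lipid droplet protein Hilpda (4.25), Procr (3.86) and the iron exporter Slc40a1 (3.84) were among the largest rises.

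How many genes that IFN-β induced were lower with spermine? Of the 2807 genes that rose with IFN-β in PBS, 1245 were lower with spermine at 3 h, against 577.6 expected for independent lists, and 364 were higher, against 559.4. Of the 2854 genes that fell with IFN-β, 945 were higher with spermine, against 568.8, and 337 lower, against 587.2. With a change of at least 1 log2 unit in both comparisons the first overlap was 279, against 40.4, which is 74.6% of the 374 genes lower with spermine. Both comparisons use the PBS 3 h libraries, so part of the excess may come from the shared control. With 1 PBS 3 h library in each comparison, so that none was shared, the overlap of 1245 genes became 969, against 394.8, or 1098, against 454.5. A mean overlap of 0 in 100 simulations of unchanged groups that shared a control sets no bound here, since such groups hold hardly any calls. Across genes, which are not independent replicates, the log2 changes had a correlation of -0.38 and a covariance of -0.23, against -0.01 in the simulations (correlation -0.50). With PBS 3 h replicate 1 in one comparison and replicate 2 in the other, the correlation was -0.32 or -0.33 and the covariance -0.20 or -0.21.

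Did the response to IFN-β itself differ between PBS and spermine? The difference of the 3 h minus 0 h changes answers this, and it takes away what spermine had already changed at rest. As lists, chemokine and cytokine genes and NF-κB genes had a smaller response with spermine, calls lost with an estimated correlation (adjusted p = 0.343 and 0.343), and the antiviral list did not pass. The NF-κB list had started higher with spermine at 0 h and was not lower as a list at 3 h. For some genes that spermine had lowered at 0 h the rise was larger. Of the 11421 genes, 1550 had a difference, 665 with a larger or less negative change with spermine and 885 with a smaller or more negative one, of which 164 and 258 differed by at least 1 log2 unit. The number was 647 and 520 without PBS 0 h replicate 1 and 2, 886 without PBS 3 h replicate 1, 753 without spermine 0 h replicate 1, and 554 and 627 without spermine 3 h replicate 1 and 2. The share above 0 was 42.9%, against 64.3% after TPM rescaling.

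Chemokines and cytokines had a negative difference in 9 of 14 genes and a positive one in 0, or 11 and 1 adjusted over the list alone (median -1.34, adjusted p = 7e-07, and adjusted p = 0.343 with an estimated correlation). Ccl5 (-2.50 ± 0.14 SE, adjusted p = 0.00122), Cxcl9 (-2.25), Tnfsf10 (-1.93) and Il27 (-1.82) led the list. With limma voom Cxcl9 (-2.65), Tnfsf10 (-0.41) and Il27 (-1.26) did not pass. NF-κB genes had 11 negative and 3 positive differences of 19, or 12 and 3 adjusted over the list alone (median -0.62, adjusted p = 0.00871, and adjusted p = 0.343 with an estimated correlation), with Ccl4 at -1.97 and the anti-inflammatory cytokine Il10 at -1.51. The NF-κB call was lost with a filter of FPKM at least 5 (median -0.59). With spermine this list was higher at 0 h (10 higher and 2 lower, median 0.40) and had no camera call at 3 h (7 and 6, median 0.10). With fry it passed at 3 h (adjusted p = 8.85e-05). Of 39 antiviral genes 9 had a negative and 3 a positive difference, or 13 and 6 adjusted over the list alone (median -0.24, adjusted p = 0.0825, and adjusted p = 0.767 with an estimated correlation). This list passed without a filter (-0.24), after TPM rescaling (-0.13) and quantile normalization (-0.30), and without PBS 0 h replicate 1 (-0.29), PBS 3 h replicate 2 (-0.30) or spermine 0 h replicate 1 (-0.24). Ifi44 (-1.54), Ifit1bl1 (-1.48), the exonuclease Isg20 (-1.26) and Rsad2 (-1.13) responded less (Ifi44 not with limma voom, -1.41), and Isg15 (0.14), Usp18 (-0.09) and Ifit1 (0.43) did not pass (without PBS 3 h replicate 1 Isg15 was -0.02, and without spermine 0 h replicate 1 it was -0.11). Usp18 passed after quantile normalization (-0.45). GTPases split into 9 negative and 4 positive differences of 16, or 10 and 4 adjusted over the list alone (median -0.73, adjusted p = 0.043, and adjusted p = 0.767 with an estimated correlation): Gbp11 (-2.11) and Gbp4 (-1.44) responded less and Irgm1 (1.17) more. With limma voom Gbp11 (-1.62) and Gbp4 (-1.31) did not pass, and the list median was 0.07. The list call was also lost with a pseudocount of 0.1 (-0.11), among protein-coding genes only (-0.68), with a filter of FPKM at least 5 and with fry (both -0.73), and without PBS 0 h replicate 2 (-0.69), PBS 3 h replicate 1 (-0.62), spermine 0 h replicate 2 (-0.70) or spermine 3 h replicate 1 (-0.70). The sensing and death list had 4 negative differences of 17, the same count adjusted over the list alone (median -0.30, adjusted p = 0.0247, and adjusted p = 0.767 with an estimated correlation). That call was lost with a pseudocount of 0.1 (-0.27), with limma voom (-0.25), with a filter of FPKM at least 5 and with fry (both -0.30), and without PBS 0 h replicate 2 (-0.21), PBS 3 h replicate 1 (-0.27), spermine 0 h replicate 1 (-0.25) or spermine 3 h replicate 1 (-0.28). MHC class I genes had 6 negative and 1 positive differences of 20, or 8 and 1 adjusted over the list alone (median -0.29, adjusted p = 0.0822), a list that passed without a filter (-0.29) and without PBS 3 h replicate 1 (-0.30) or spermine 0 h replicate 1 (-0.28). The receptor and kinase list had 1 negative and 5 positive differences of 14, or 3 and 5 adjusted over the list alone, with a median of -0.25, a mean of -0.01 and a test pointing up (adjusted p = 0.97).

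Single genes of the pathway also differed in their response. Socs1 rose from 0.159 ± 0.00820 to 204 ± 65.7 FPKM with PBS and from 0.512 ± 0.372 to 73.7 ± 8.69 with spermine (difference -1.79 ± 0.34 SE, adjusted p = 0.0197). The Socs1 call was lost with limma voom (-2.90), without a filter (-1.79) and without PBS 0 h replicate 1 (-1.79) or 2 (-1.78) or spermine 3 h replicate 1 (-1.91) or 2 (-1.67). Cxcl10 (-1.0, adjusted p = 0.0136) lost its call with a pseudocount of 0.1 (-0.87), with limma voom (-0.84) and without PBS 0 h replicate 2 (-0.88) or spermine 3 h replicate 1 (-0.99) or 2 (-1.0). Mx1 (-0.88, adjusted p = 0.0212) lost it with a pseudocount of 0.1 (-0.84), without a filter (-0.88) and without PBS 0 h replicate 2 (-0.76), PBS 3 h replicate 1 (-0.77), spermine 0 h replicate 1 (-0.76) or spermine 3 h replicate 1 (-0.85) or 2 (-0.91). Irf1 responded more with spermine (1.83, adjusted p = 0.00132), from 2.50 ± 0.224 to 258 ± 6.18 FPKM against 6.08 ± 0.343 to 146 ± 7.23. Irf8 (1.28) and Tap1 (1.11) also responded more, and both had been lower with spermine at 0 h. The feedback list as a whole had 3 positive and 1 negative differences of 10, or 4 and 3 adjusted over the list alone (median 0.02, adjusted p = 0.589). With fry the feedback list passed for the difference (adjusted p = 0.0431). Cx3cr1 had the largest positive difference of the named genes (2.42): it fell from 11.5 ± 0.00839 to 1.71 ± 0.187 FPKM with PBS, and with spermine it was at 1.32 ± 0.00623 at 0 h and 1.69 ± 0.237 at 3 h. Zfp36l1, which destabilises mRNAs (2.08), and the deglycosylating enzyme Engase (2.07) showed the same order. Tnfsf8 (-2.24) and Sectm1a (-2.77) responded less, and Sectm1a and Gbp11 are listed at 0 in both spermine 0 h libraries, so their fitted differences depend on the pseudocount. With limma voom neither Tnfsf8 (-1.52) nor Sectm1a (-3.08) passed. The NRF2, integrated stress and heat shock lists did not pass for the difference (medians 0.02, 0.09 and -0.01, adjusted p = 0.737, 0.589 and 0.737), though some members did: 2 positive and 3 negative of 18, 3 and 1 of 19, and 1 and 0 of 10, or 3 and 3 for NRF2 adjusted over the list alone and the same counts for the others. Nor did the polyamine list pass (-0.06, adjusted p = 0.737; 1 and 2 of 22, the same over the list alone).

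**Figure D3:**
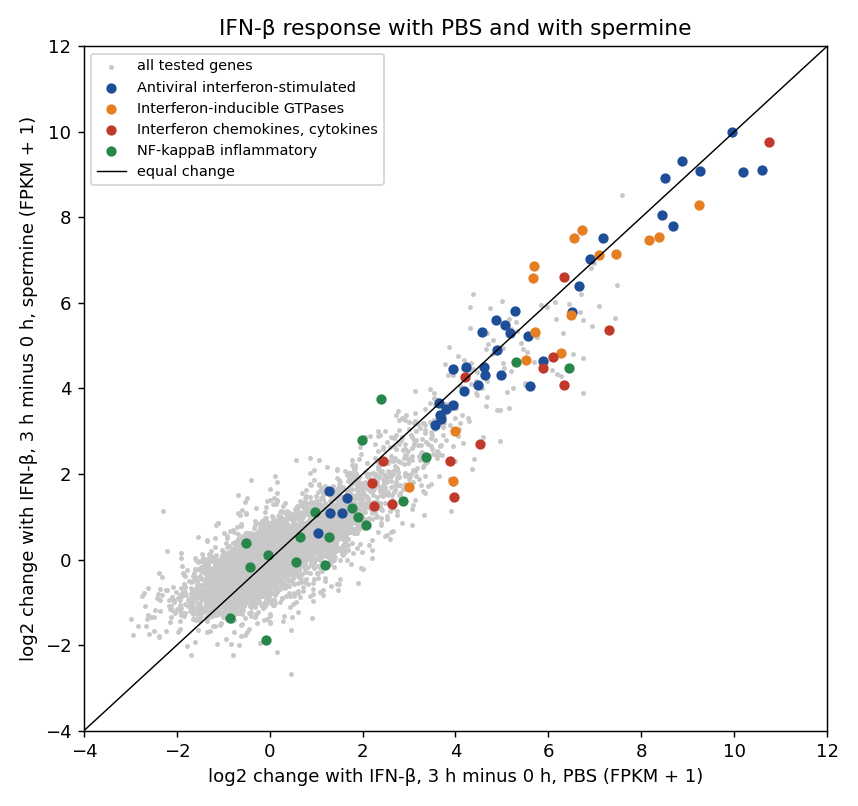
Log2 change of FPKM + 1 from 0 h to 3 h of IFN-β with PBS (horizontal) and with spermine (vertical) for the 11421 genes tested (grey), with 4 gene lists coloured and a line of equal change. Most chemokine and cytokine genes lie under the line (median difference -1.34), while antiviral genes lie on both sides of it (median -0.24).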

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

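The tests of the explanations weighed here were all chosen after the results were seen, and so were the differences of genes that the fixed rule names in other comparisons only. The limma test of the difference itself showed that the response to IFN-β differed between spermine and PBS for 65 of the 107 genes named in the text and for 8 of the 24 lists. The rule names genes partly for their change in this comparison, so that share is high by selection, and over all 11421 genes tested 1550 differed, or 13.6%. Values are log2 differences, spermine minus PBS.

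Of the 65 genes 34 had a smaller or more negative response with spermine. Among chemokine, cytokine and inflammatory genes these were Ccl5 (-2.50), Cxcl9 (-2.25), Tnfsf8 (-2.24), Ccl4 (-1.97), Tnfsf10 (-1.93), Il27 (-1.82), Il10 (-1.51), Cxcl10 (-1.0), Tnf (-0.91), Ptgs2 (-0.74) and Cd40 (-0.70). Among antiviral genes and GTPases they were Gbp11 (-2.11), Ifi44 (-1.54), Ifit1bl1 (-1.48), Gbp4 (-1.44), Isg20 (-1.26), Rsad2 (-1.13), Iigp1 (-0.95), Mx1 (-0.88) and Gbp2 (-0.85). Of sensing, presentation and feedback genes Socs1 (-1.79), Tlr3 (-1.07), Ifi205 (-0.90) and H2-T24 (-0.76) belonged to them. The others were Sectm1a (-2.77), P2ry13 (-1.68), Pfkfb3 (-1.19), Clec10a (-1.05), Spry3 (-0.91), Hspa5 (-0.88), Ednrb (-0.88), Sms (-0.70), Fosl1 (-0.63) and Gclc (-0.36). A negative difference is not in itself a lower level at 3 h. Tnf, Ptgs2, Pfkfb3, Clec10a, Hspa5, Ednrb, Fosl1 and Gclc had been higher with spermine at 0 h, and Ptgs2 was still higher at 3 h. Ccl5, Cxcl9, Tnfsf10, Il27 and Cxcl10 were lower with spermine at 3 h. Sectm1a and Gbp11 are listed at 0 in both spermine 0 h libraries, so their values depend on the pseudocount. P2ry13, Spry3 and Ifi205 lost call and most of their size with a pseudocount of 0.1 (-0.37, -0.10 and -0.40) and their sign with limma voom (0.45, 0.37 and 0.11). With limma voom Tnfsf10 (-0.41), H2-T24 (-0.41), Fosl1 (-0.39) and Tlr3 (-0.65) shrank and lost their call, and so did Gclc after TPM rescaling (-0.23).

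The other 31 genes had a larger or less negative response with spermine. In the interferon pathway these were Irf1 (1.83), Irf8 (1.28), Irgm1 (1.17), Tap1 (1.11), Ifi47 (0.98), Igtp (0.97), Irgm2 (0.93), Ptpn6 (0.80), Parp14 (0.73), Stat2 (0.71), Irf9 (0.54), Ifnar2 (0.47) and Ifnar1 (0.44). Ptpn6 and Stat2 were still lower with spermine at 3 h (-0.97 and -0.39). Irf9 (0.13) and Ifnar1 (-0.08) did not pass at 3 h. Irf1 and, with a call that depends on the scaling, Ifnar2 were higher at 3 h. Spermine had lowered Irf1, Irf8, Tap1, Irgm2, Ifi47 and Parp14 at 0 h, which by itself makes the difference more positive. A positive difference is therefore not a higher level at 3 h. Ifnar1 lost its call whichever library was left out (0.38 to 0.49), without a filter and without a trend (both 0.44). Stat2 (0.54 to 0.81) and Irf9 (0.42 to 0.60) lost theirs without each library except spermine 0 h replicate 2. Both also lost it without a filter, without a trend and after quantile normalization (0.66 and 0.48). Il6 (1.36) and Il1b (0.92) were inflammatory genes with a larger response, though Il6 was 0.76 with a pseudocount of 0.1, -1.15 with limma voom and past the threshold with neither. Il1b lost its call without a filter (0.92) and without PBS 0 h replicate 1 (0.79) or 2 (1.04) or PBS 3 h replicate 2 (0.80). It also lost it without spermine 0 h replicate 2 (0.77) or spermine 3 h replicate 1 (0.90) or 2 (0.93). Of the others, Ddit4 (1.24), Hspa1a (1.22), Osgin1 (0.98) and Srxn1 (0.63) are stress genes. The rest were Cx3cr1 (2.42), Zfp36l1 (2.08), Engase (2.07), Enc1 (1.97), Sesn1 (1.92), Slc26a11 (1.89), S1pr1 (1.59), Fgd3 (1.29), Tor4a (0.90), Tgfbr1 (0.88), Hist2h2be (0.81) and Srm (0.68). Of the 65 differences 27 kept their call and sign in every alternative that gave them a value. The number that kept them was 43 with limma voom, 49 without a filter, 52 with a pseudocount of 0.1, 59 without a trend, 61 after quantile normalization and 64 after TPM rescaling. It was 44 and 43 without PBS 0 h replicate 1 and 2, 53 and 57 without those of PBS 3 h, 49 and 58 without those of spermine 0 h, and 39 and 42 without those of spermine 3 h.

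The lists with a negative difference were interferon-inducible chemokines and cytokines (median -1.34), GTPases (-0.73), NF-κB genes (-0.62) and nucleic acid sensing, inflammasome and lytic death genes (-0.30). Of these the NF-κB list was not lower with spermine at 3 h (median 0.10). The lists with a positive difference were replication-dependent histones (0.69), immediate early genes (0.37), sterol efflux (0.29) and macrophage identity (0.20). Few of their members passed alone: 1 of 4 histones, 4 immediate early genes with a positive and 1 with a negative difference of 12, 3 of 10 sterol efflux genes and 1 of 14 macrophage identity genes, Cx3cr1 (3, 4 and 1, 4 and 1 adjusted over the list alone). With an estimated correlation all 8 had an adjusted p of 0.343 or more. A filter of FPKM at least 5 ended every list call but that of the chemokines: NF-κB genes (-0.59), GTPases (-0.73), sensing and death genes (-0.30), sterol efflux (0.29), immediate early genes (0.43), macrophage identity (0.20) and histones (0.69). A pseudocount of 0.1 ended those of GTPases (-0.11), sensing and death genes (-0.27), macrophage identity (0.20) and histones (0.76), and limma voom those of GTPases (0.07), sensing and death genes (-0.25) and histones (0.77). TPM rescaling ended those of immediate early genes (0.42) and histones (0.82), quantile normalization that of immediate early genes (0.44), and fry, which leaves medians as they are, those of GTPases, sensing and death genes, immediate early genes and histones. Among protein-coding genes only GTPases (-0.68), immediate early genes (0.37), macrophage identity (0.20) and histones (0.69) did not pass. Sterol efflux lost its call without PBS 0 h replicate 2 (0.18) or PBS 3 h replicate 1 (0.11). Immediate early genes lost it without PBS 0 h replicate 2 (0.27), PBS 3 h replicate 1 (0.23), spermine 0 h replicate 1 (0.14) or spermine 3 h replicate 1 (0.32). Macrophage identity lost it without PBS 0 h replicate 1 (0.18) or 2 (0.19), PBS 3 h replicate 2 (0.19), spermine 0 h replicate 2 (0.17), or spermine 3 h replicate 1 (0.20) or 2 (0.19). Histones lost it without PBS 0 h replicate 2 (0.57), either PBS 3 h library (0.55 and 0.71), spermine 0 h replicate 1 (0.46) or either spermine 3 h library (0.68 and 0.66). Only 4 of the 12 listed histone genes passed the filter in these poly(A)-selected libraries, so the list is poorly measured. GTPases and sensing and death genes depend on single libraries as the report gives, with lowest sizes of -0.62 without PBS 3 h replicate 1 and -0.21 without PBS 0 h replicate 2.

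The first pattern weighed is the smaller response of chemokine and cytokine genes with spermine. A difference in library scaling as the whole cause is argued against by the median nearest 0 over TPM rescaling, median-of-ratios rescaling, quantile normalization and limma voom, which was -1.18. Of these, median-of-ratios rescaling and limma voom use the scale that the deposited values already carry. Only TPM rescaling and quantile normalization change it. The pseudocount is argued against in the same way by a median of -1.36 with a pseudocount of 0.1. A loss of response shared evenly by interferon-induced genes is argued against by the gap between the medians of this list and of the antiviral genes, which responded about as strongly in PBS (medians 4.37 and 4.90). The gap was -1.103, with a 95% interval over 10000 resamples of members from -1.58 to -0.31, and -0.835 at its nearest to 0 over the alternatives. That interval treats members as independent, and the list's own call did not hold with an estimated correlation (adjusted p = 0.343). For the levels at 3 h the same gap was -0.495, from -1.34 to 0.19, an interval that holds 0. The argument therefore covers the response and not the level at 3 h. At 0 h the medians with spermine were -0.34 for the antiviral and 0.01 for the chemokine and cytokine list, so part of the gap may come from 0 h. GTPases (median difference -0.73) were not compared in this way. Weaker signalling through JAK1, which the series title names, may be at work, but RNA levels at 1 time point do not test it.

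The pattern of NRF2 genes higher with spermine at both times was weighed next. Library scaling as the whole cause is argued against by the lowest list median over the same 4 settings and both times, 1.72. Again only TPM rescaling and quantile normalization among them change the scale. Oxidation products of spermine, which amine oxidases in serum make, could raise the same genes, and heat shock genes, which such products would also raise, had a median of 1.10 at 0 h. Spermine and its oxidation products cannot be told apart here, because no arm leaves out serum or blocks the oxidases, and the medium is not given in the sources used here.

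The last pattern is the lower level of antiviral genes with spermine at 0 h. Reads carried over from the 3 h libraries could raise the low PBS 0 h level, but Serpina3g, at 0.0104 FPKM at 0 h and 77.8 at 3 h in PBS, bounds such carry-over at 0.0133% of the 3 h level. That supplies 0.39% of the PBS 0 h level of the median of the 18 lower genes, and 19.4% for the most affected, Cmpk2. Library scaling is 1 factor per library, but on FPKM + 1 it moves genes near or below 1 FPKM less than others. At 0 h TPM rescaling took the GTPase median from -0.19 to -0.29, while the median shift over all genes was -0.30. The gap between the antiviral list's median change and that of all genes was -0.356, with a 95% interval over 10000 resamples of members, taken as independent, from -0.49 to -0.07. Since this gap takes low and high members alike, it does not settle whether scaling is the whole cause, and it was not computed under another scaling. Less interferon signalling at rest is a candidate explanation that was not tested further, and with an estimated correlation the list as a whole did not pass (adjusted p = 0.512).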

How the results depend on the processing

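The crossed pairing of replicate numbers, the alternatives for the overlap and those for every list and comparison were chosen after seeing the data, and the others before the data were examined. Median-of-ratios rescaling changed the counts by a few genes at most, since the deposited values already carry that scaling. TPM rescaling left 21.1%, 21.5%, 20.1%, 26.4% and 64.3% of changed genes higher, against 49.6%, 47.1%, 53.3%, 49.2% and 42.9% as reported (IFN-β in PBS, with spermine, spermine at 0 h, at 3 h, difference).

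Of the 100 counts of changed genes under the alternatives 87 stayed within 1.5 times the count reported and 13 moved. A limit of 1 log2 unit gave 1755 and 1069 genes for IFN-β in PBS and with spermine, 750 and 820 for spermine at 0 h and 3 h, and 422 for the difference, and it lowered the overlap to 279, as a stricter limit must. Leaving out 1 library gave 4318 to 5676 and 3180 to 4923 genes for IFN-β in PBS and with spermine, 2999 to 4897 and 2912 to 4645 for spermine at 0 h and 3 h, 520 to 1671 for the difference, and an overlap of 896 to 1253. The overlap was 969 or 1098 with the shared libraries split. Fewer libraries leave fewer degrees of freedom.

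At 3 h the lower antiviral median of -0.52 and GTPase median of -0.82 kept their direction in every alternative and lost their adjusted p only with an estimated correlation. Without 1 library they ranged from -0.65 to -0.40 and from -0.93 to -0.71. The median difference of response of the antiviral genes, not past the threshold as reported, passed without a filter (-0.24), after TPM rescaling (-0.13) and after quantile normalization (-0.30), and ranged from -0.30 to -0.17 without 1 library. That of the GTPases lost its adjusted p with a pseudocount of 0.1 (-0.11), a filter of FPKM at least 5 (-0.73), protein-coding genes only (-0.68), an estimated correlation (-0.73) and fry (-0.73), and reversed with limma voom (0.068). It ranged from -0.84 to -0.62 without 1 library and lost its adjusted p in 4 of those 8 fits. Several GTPase genes lie under 1 FPKM at 0 h, where the pseudocount decides the fold, and the cause of the other changes was not tested.

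Reversals by scaling concerned lists and genes with small changes. TPM rescaling gave MHC class II -0.002 for IFN-β with spermine and -0.046 for spermine at 0 h, and the lysosome -0.081 for spermine at 0 h. Quantile normalization gave MHC class II -0.073 and -0.034 there, the lysosome -0.41 for IFN-β in PBS, -0.17 for spermine at 0 h and 0.20 for the difference, and macrophage identity -0.38 for spermine at 0 h. The test of fry pointed against camera's for glycolysis with IFN-β in PBS (-0.070). Jak1 with IFN-β in PBS became -0.16 after TPM rescaling and -0.12 after quantile normalization, and with spermine at 0 h -0.067 after TPM rescaling. Ifnar2 with IFN-β in PBS became -0.28 and -0.26. TPM rescaling multiplies all genes of a library by 1 factor, which can turn small changes around, and the cause of the reversals after quantile normalization was not tested. With limma voom the differences of Ifi205 (0.10), Spry3 (0.37), Il6 (-1.15) and P2ry13 (0.45) reversed, all genes with a level under 2 FPKM in 1 group or more, and the cause was not tested.

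Of the 247 pairs of a named gene and a comparison 238 were changed, and of these 187 kept call and sign in every alternative and 51 lost it in at least 1. Over the list tests other than the 4 list medians given above 2220 results stayed, 115 weakened, 51 of them with an estimated correlation, 69 strengthened, 34 of them with fry, and 10 reversed. For those 4 medians 64 stayed, 11 weakened, 6 strengthened and 1 reversed.

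The titles number the libraries BM1 and BM2, and the labels do not say whether a number names the same animal across groups. Correlations of replicate deviations were 0.23, 0.25 and 0.37 among PBS 0 h, PBS 3 h and spermine 0 h, and -0.06, -0.09 and -0.13 with spermine 3 h, so a pairing by number is not shown and stays open. With the replicate number as a block 5956 and 5033 genes changed with IFN-β in PBS and with spermine, 4996 and 4978 with spermine at 0 h and 3 h, and 1813 for the difference, where those of Irf9, Fosl1 and Srm, at unmoved values, no longer passed. A crossed pairing, chosen after seeing the data, gave 5866 for IFN-β with spermine.

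Depth limits the genes near 1 FPKM, which the filter removes below that level. In simulated data with this number of libraries 26.2% of 2-fold differences of response were recovered.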

Other observations

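The hypotheses weighed above were all tested after the results were seen, and the lists below were fixed before the data were examined.

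Genes of metabolism beyond those in the report were higher with spermine. Of 20 genes of glycolysis and hypoxia 16 were higher and 1 lower with spermine at 0 h (median 0.71, adjusted p = 2.69e-06; 17 and 1 adjusted over the list alone) and 18 and 1 at 3 h (0.79, 2.51e-07; the same over the list alone), with adjusted p = 0.199 and 0.169 with an estimated correlation. The glucose transporter Slc2a1 was higher by 2.15 and 2.06, Pfkfb3, which makes the activator of phosphofructokinase, by 1.91 at 0 h, and Hilpda, a lipid droplet protein induced by low oxygen, by 4.25 at 3 h. Egln3, an oxygen sensor, fell by 1.93 with IFN-β in spermine, where the list had a median of -0.13 (adjusted p = 0.667; -0.07, 0.805 in PBS). Of 23 cholesterol biosynthesis genes 12 were higher and 3 lower at 0 h (0.33, 0.029) and 13 and 1 at 3 h (0.36, 0.00559), the same numbers over the list alone, with adjusted p = 0.199 and 0.169 with an estimated correlation. Insig1, which holds the pathway back, was higher by 1.46 and 1.40. With IFN-β the list was lower, with a median of -0.22 (0.0298; 0.179 with an estimated correlation) in PBS, a call lost without PBS 0 h replicate 2 (-0.18), and of -0.35 (0.0124; 0.145) with spermine. Sterol efflux genes did not pass with camera in the single comparisons, and at 0 h their median of 0.12 and mean of -0.09 had opposite signs, as did -0.19 and 0.04 for IFN-β with spermine. With fry they passed for IFN-β in PBS and for spermine at 3 h (adjusted p = 0.00175 and 0.0021).

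Of 14 genes of the unfolded protein response 11 were higher with spermine at 0 h (0.57, adjusted p = 4.23e-05; 12 over the list alone) and 8 at 3 h (0.32, 0.000782; 10), with adjusted p = 0.117 and 0.169 with an estimated correlation. The chaperone Hspa5 was higher by 1.27 at 0 h and its partner Dnajb9 by 1.45 and 1.36. Immediate early genes were higher at 0 h (0.68, 0.0292; 7 higher and 3 lower of 12), a call lost without spermine 0 h replicate 2 (0.65) or in a fit of only the 2 groups (0.68), and at 3 h (1.11, 0.00127; 7 and 1, or 8 and 2 over the list alone), with adjusted p = 0.512 and 0.353 with an estimated correlation. The phosphatase Dusp1 was higher by 3.08 and 3.32 and Ier3 by 2.91 and 3.06. With IFN-β in spermine they were higher by 0.77 (0.00536; 0.434 with an estimated correlation). Lysosome genes were higher at 0 h (0.27, 0.00777; 12 and 1 of 23) and at 3 h (0.22, 0.00225; 10 and 1), with adjusted p = 0.199 and 0.169 with an estimated correlation, but the 0 h median was -0.17 after quantile normalization and -0.081 after TPM rescaling, and over the list alone 13 and 12 were higher. The autophagy receptor Sqstm1 was higher by 2.35 and 2.80. MHC class II genes were higher at 0 h (0.27, 0.0327; 4 of 8) and with IFN-β in spermine (0.33, 0.0431; 5 of 8, or 6 higher and 1 lower over the list alone), with adjusted p = 0.199 and 0.173 with an estimated correlation, and both turned negative after TPM rescaling (-0.046 and -0.002) and quantile normalization (-0.034 and -0.073). Those calls were lost without PBS 0 h replicate 1 (0.26) or spermine 0 h replicate 2 (0.30) at 0 h, and without spermine 0 h replicate 2 (0.36) or spermine 3 h replicate 2 (0.39) with IFN-β. They were also lost with limma voom (0.30) at 0 h, and at 0.33 without a trend and among protein-coding genes only with IFN-β. In PBS 5 of the 8 MHC class II genes were higher with IFN-β too (median 0.26, adjusted p = 0.0623). There the list passed without a filter (0.29) and with a replicate block (0.26). Alternative activation genes were higher at 0 h (0.43, 0.0228; 4 of 8; 0.339 with an estimated correlation), Clec10a by 1.56, and the receptor Il4ra was higher by 1.22 at 3 h. Histone genes were lower at 0 h (-0.54, 0.0284; 3 of 4; 0.339 with an estimated correlation), with Hist2h2be at -0.95. The histone call was lost without a filter (median -0.08), and only 4 of the 12 listed histone genes passed the filter in these poly(A)-selected libraries. A filter of FPKM at least 5 ended the 0 h calls of the immediate early (0.68), lysosome (0.27), MHC class II (0.29) and alternative activation genes (0.91) and the cholesterol call for IFN-β in PBS (-0.19). TPM rescaling ended the histone call (-0.86) and the lysosome's at 3 h (0.01), which quantile normalization also ended (0.07).

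The other lists did not pass for spermine: the cell cycle (-0.12 at 0 h and -0.01 at 3 h), macrophage identity (0.02, with a mean of -0.18, and 0.21) and mitochondrial mRNAs (0.23 and -0.17). After quantile normalization macrophage identity was lower at 0 h (-0.38), and with fry it passed at both times. Mitochondrial mRNAs passed at 0 h without spermine 0 h replicate 2 (0.41), and stood at -0.002 without replicate 1, -0.12 after TPM rescaling and -0.11 after quantile normalization. The antibody receptor Fcgr1 rose with IFN-β in PBS (3.55), and Cx3cr1 fell by 2.43 with spermine at 0 h. Among markers of other cells those of lymphocytes, erythroid cells, stroma, and mast cells and basophils had no measurable gene, the highest lymphocyte marker being Cd79b at 0.844 FPKM in 1 library. Those of neutrophils and osteoclasts went both ways: of 5 measured neutrophil markers 2 were higher and 1 lower with spermine at 0 h (median 0.34) and 1 and 1 at 3 h (-0.27), and of 4 measured osteoclast markers 1 and 1 at 0 h (-0.04) and 2 and 0 at 3 h (0.22). Of 3 measured dendritic cell markers 1 was higher at each time (0.14 and 0.09), and 2 rose with IFN-β both in PBS and with spermine (0.78 and 0.73).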
